A study of Mus musculus with 39 samples.

How the data were processed

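Expression was measured by RNA sequencing in 39 mouse libraries: 10 of hepatocytes isolated from the liver, 21 of monocytes sorted from bone marrow and 8 of monocytes sorted from the spinal cord of mice with EAE. Fed and fasted mice were compared after 4 h and 12 h (hepatocytes), after 4 h and 17 h (bone marrow), and after 4 weeks of fasting cycles (spinal cord); CCR2-/- mice were compared with C57BL/6 mice, all of them fed. Per the labels, reads were quantified by the authors with kallisto 0.44.0 against GRCm38, and 1 file was deposited for each library. The deposited values have the properties of TPM summed to genes: each library sums to 982922 to 994023, and the values are not whole numbers. Counts scaled to the library total alone are not fully excluded by the values. The transcript annotation, the way transcripts were summed, and the filter that left 8980 to 9449 genes per experiment are not given in the sources used here. Genes with near-identical copies, such as Chil3 and Chil4, Hba-a1 and Hba-a2, or Cyp4a10 and its neighbors, depend on how reads were divided between them.

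Gene symbols that a spreadsheet had turned into dates (13 to 15 per experiment) were left out, which left 8966 genes for hepatocytes, 9434 for bone marrow at 4 h, 9134 for bone marrow at 17 h, 9210 for CCR2-/- and C57BL/6 and 9079 for spinal cord. Values were transformed as log2(TPM + 1), with genes of a mean of at least 1 TPM tested (9428 of 9434 in bone marrow at 4 h, all genes elsewhere). Groups were compared with limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust empirical Bayes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. The 10 hepatocyte libraries were fitted together with 4 groups; each monocyte experiment was fitted alone, except for the interaction of fasting with time, which was fitted over the 15 bone marrow libraries of 4 h and 17 h and 8844 genes. A test for counts had been foreseen and was not used, since the values are not whole numbers and were taken as TPM. The number of reads is not given in the sources used here, so depth is unknown and no counting error can be given: precision was taken only from the spread between libraries. The labels do not say whether libraries of a group come from separate animals, and p-values measure the spread between libraries whatever their origin.

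Of 53 gene lists written before the data were examined, those with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes, with adjustment over the lists of 1 comparison, and again with the correlation estimated per list. For each list the text gives the number of members called over all genes and the number called when adjusted over the list alone. A list's median is given relative to the median of all genes. Genes were named by a rule: those called, with groups that do not overlap and a mean of at least 10 TPM in the higher group, the 8 with the highest and the 8 with the lowest log2 fold change; up to 4 members of each list that passed or held several called genes; and a set of key genes of fasting and of monocyte traffic. Of the key genes, Ccl2 in hepatocytes, S100a8 and Pdk4 in bone marrow, Il1b in bone marrow of fed and fasted mice, Ccl2 in bone marrow at 4 h, Tnf in bone marrow at 17 h, and Il1a, Nos2, Arg1, Cd274 and Pdk4 in spinal cord are not analysed here. Some genes that the rule named are not reported here.

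The fits were tested on simulated data with 100 genes changed at each of 2 sizes in each comparison. Noise was drawn for each gene alone, with no shift shared across a library. The recovered shares and false calls therefore do not speak to library-wide shifts. At a log2 fold change of 1, limma recovered 61% (hepatocytes 4 h), 53% (hepatocytes 12 h), 83% (bone marrow 4 h), 82% (bone marrow 17 h), 85% (CCR2-/-) and 9% (spinal cord) of them, with 1 to 13 false calls; at a log2 fold change of 2 it recovered 84%, 94%, 99%, 99%, 99% and 68%. For the interactions the shares were 37% and 74% in hepatocytes and 80% and 100% in bone marrow. Correlations between comparisons were computed across the genes tested in both.

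The alternatives tried were quantile normalization, limma without a trend, no filter, empirical Bayes that is not robust, a pseudocount of 0.1, the replicate number as a block, hepatocytes of 1 time alone, a z of the difference of separate fits for the bone marrow interaction, each library left out in turn, fry in place of camera, camera with the block, and, for correlations, a mean of at least 10 TPM or Spearman's rho. Chosen after the data were seen were libraries centred on their median, removal of each library's trend of log2 value on median transcript length (GENCODE M21, loess with a span of 0.5), a mean of at least 10 TPM for genes, fed spinal cord libraries 3 and 4 as the only fed ones, and leaving out genes listed at 0. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.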

Results

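RNA of mouse liver cells and monocytes was sequenced in 39 libraries, in 5 experiments that compare fed with fasted mice or C57BL/6 with CCR2-/- mice. Hepatocytes came from livers of mice kept for 4 h with food (n = 3) or without it (n = 2), and for 12 h with food (n = 2) or without it (n = 3). Monocytes sorted from bone marrow came from mice fed or fasted for 4 h (n = 4 and 4), from mice fed or fasted for 17 h (n = 3 and 4), and from fed C57BL/6 and CCR2-/- mice (n = 3 and 3). Monocytes sorted from spinal cord came from mice with experimental autoimmune encephalomyelitis (EAE), an induced inflammation of the central nervous system, that were fed (n = 4) or fasted in cycles for 4 weeks (n = 4). Expression was taken to be in TPM, transcript abundance scaled for length and library total, for 8966 to 9434 genes per experiment. The unit was read from the values, and counts scaled to the library total alone, not for length, are not fully excluded. The number of reads behind each value is not given in the sources used here, so the depth is unknown. Values after ± are SDs over libraries.

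The first question was what 4 h without food does to gene expression in hepatocytes. Genes of fatty acid use rose. Angptl4, which encodes a secreted inhibitor of lipoprotein lipase, was at 326 ± 48.4 TPM (SD, n = 2) in fasted and 27.5 ± 5.48 TPM (SD, n = 3) in fed hepatocytes (log2 fold change 3.53, SE 0.15, adjusted p = 1.2e-06). The fatty acid hydroxylase Cyp4a14 rose from 191 ± 8.93 to 616 ± 72.5 TPM (log2 fold change 1.68, SE 0.07, adjusted p = 1.2e-06). Cpt1a, which brings fatty acids into mitochondria for oxidation, rose from 56.8 ± 2.83 to 89.0 ± 16.9 TPM (log2 fold change 0.63, SE 0.11, adjusted p = 0.0021). The lipid droplet protein Plin2 rose from 544 ± 22.3 to 1232 ± 83.2 TPM (log2 fold change 1.18, SE 0.05, adjusted p = 1.8e-06). No fed library overlapped a fasted library for any of these genes. Fgf21, a hormone of fasting, was at 12.2 and 1.98 TPM in the fasted libraries and at 0.755, 0 and 0.153 TPM in the fed libraries. Of 42 measured PPARA targets and fatty acid oxidation genes, 19 rose and 9 fell (19 rose and 11 fell when adjusted over the list alone). The median of the list was 0.47 above that of all genes (camera adjusted p = 2.0e-05, and adjusted p = 0.21 with an estimated correlation). Ppara itself rose (log2 fold change 0.58, SE 0.14, adjusted p = 0.011), a call that ended at adjusted p = 0.0754 when only the 5 libraries of this time were fitted (range over its alternatives 0.0024 to 0.0754). The pyruvate dehydrogenase kinase Pdk4 did not pass (log2 fold change 0.29, SE 0.24, adjusted p = 0.38).

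Genes of lipid synthesis fell in the same libraries. Srebf1, which drives lipogenic genes, fell (log2 fold change -1.07, SE 0.12, adjusted p = 1.7e-04). Fatty acid synthase, Fasn, fell (log2 fold change -1.24, SE 0.21, adjusted p = 0.0021), and so did the stearoyl-CoA desaturase Scd1 (log2 fold change -1.06, SE 0.07, adjusted p = 1.3e-05). Hmgcs1, an early enzyme of cholesterol synthesis, fell from 146 ± 17.4 to 25.8 ± 0.753 TPM (SD, n = 3 fed and 2 fasted; log2 fold change -2.45, SE 0.11, adjusted p = 1.3e-06). Mvd, a later one, fell from 99.7 ± 1.78 to 9.41 ± 4.06 TPM (log2 fold change -3.33, SE 0.25, adjusted p = 2.2e-05). Of 16 measured de novo lipogenesis genes 15 fell, and of 24 cholesterol synthesis genes 19 fell. None rose, and the counts were the same when adjusted over each list alone. The medians were -0.79 and -0.92 relative to all genes (camera adjusted p = 8.7e-07 for both, and adjusted p = 0.070 with an estimated correlation). Cyp7a1, the first enzyme of bile acid synthesis, fell from 26.1 ± 1.80 to 6.46 ± 0.52 TPM (log2 fold change -1.86, SE 0.12, adjusted p = 9.8e-06).

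Genes of amino acid breakdown, protein folding and growth hormone response fell as well, while the gluconeogenic genes Pck1 and G6pc rose. The urea cycle enzyme Cps1 fell from 1076 ± 65.3 to 447 ± 14.2 TPM (SD, n = 3 fed and 2 fasted; log2 fold change -1.26, SE 0.06, adjusted p = 1.8e-06). The chaperone Hspa5 fell from 835 ± 46.4 to 241 ± 20.8 TPM (log2 fold change -1.79, SE 0.07, adjusted p = 8.2e-07). Cish, a target of growth hormone signalling, fell from 30.2 ± 1.71 to 2.24 ± 0.336 TPM (log2 fold change -3.27, SE 0.16, adjusted p = 3.4e-06). Pck1, the enzyme that commits to gluconeogenesis, rose from 319.8 ± 27.9 to 738 ± 87.6 TPM (log2 fold change 1.20, SE 0.09, adjusted p = 2.3e-05). G6pc, which releases glucose, rose from 145 ± 3.28 to 187 ± 3.24 TPM (log2 fold change 0.36, SE 0.06, adjusted p = 0.0018). The gluconeogenesis list as a whole did not pass (3 of 13 rose and 7 fell, 3 rose and 9 fell over the list alone; camera adjusted p = 0.30, and adjusted p = 0.64 with an estimated correlation). Of 20 amino acid catabolism and urea cycle genes 16 fell and none rose (18 fell when adjusted over the list alone; camera adjusted p = 2.8e-07, and adjusted p = 0.15 with an estimated correlation). Of 21 heat shock and unfolded protein response genes 16 fell and 2 rose (17 fell and 2 rose over the list alone; camera adjusted p = 4.8e-05, and adjusted p = 0.070 with an estimated correlation). Of 15 growth hormone responsive and sex-biased genes 8 fell and 2 rose (2 rose and 10 fell over the list alone; camera adjusted p = 0.023, and adjusted p = 0.13 with an estimated correlation). Of 16 immediate early genes, which also rise during cell isolation, 9 rose and 2 fell (9 rose and 2 fell over the list alone; camera adjusted p = 5.0e-04, and adjusted p = 0.25 with an estimated correlation). Ier2 was among those that rose (log2 fold change 0.90, SE 0.09, adjusted p = 1.2e-04).

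Genes of macrophages and endothelium were higher in the fasted 4 h libraries. The macrophage gene C1qb rose from 326 ± 21.9 to 583 ± 39.7 TPM (SD, n = 3 fed and 2 fasted; log2 fold change 0.84, SE 0.08, adjusted p = 1.1e-04). The sinusoidal endothelial gene Clec4g rose from 182 ± 9.43 to 328 ± 25.1 TPM (log2 fold change 0.85, SE 0.08, adjusted p = 9.2e-05), and the MHC class II chaperone Cd74 rose from 702 ± 14.4 to 1267 ± 36.5 TPM (log2 fold change 0.85, SE 0.07, adjusted p = 3.7e-05). The summed TPM of 14 Kupffer cell and macrophage markers was 1659, 1645 and 1623 in fed and 2574 and 2659 in fasted libraries. Of these markers 7 rose and none fell (7 rose and 0 fell over the list alone; camera adjusted p = 2.3e-05, and adjusted p = 0.070 with an estimated correlation). Of 13 endothelial markers 11 rose (11 rose and 1 fell over the list alone; camera adjusted p = 2.6e-07, and adjusted p = 0.069 with an estimated correlation). Erythroid markers went the other way, with 3 of 7 lower and none higher (0 rose and 3 fell over the list alone) at a median of -0.72 relative to all genes, and the list did not pass (camera adjusted p = 0.15, and adjusted p = 0.51 with an estimated correlation). Of 8 MHC class II genes 6 rose (6 rose and 0 fell over the list alone; camera adjusted p = 2.0e-05, and adjusted p = 0.070 with an estimated correlation). Of 10 mitochondrially encoded genes 8 rose (8 rose and 0 fell over the list alone; camera adjusted p = 1.9e-09, and adjusted p = 0.069 with an estimated correlation). In all, 3331 of 8966 genes changed, 928 up and 2403 down, at a median log2 fold change of -0.22, so each change above is 0.22 higher relative to the median gene. The split was 1124 up and 1394 down after quantile normalization and 1429 up and 1433 down after a length trend was removed. The groups did not overlap for 53.7% of genes, against 20% by chance. With only the 5 libraries of this time in the fit, 1744 genes changed, 507 up and 1237 down. Each SE and p-value of the main fit rests on a spread pooled over all 10 hepatocyte libraries. The fasted 4 h libraries were less alike, with a correlation of 0.917, against 0.964 to 0.992 within the other hepatocyte groups.

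**Figure D1:**
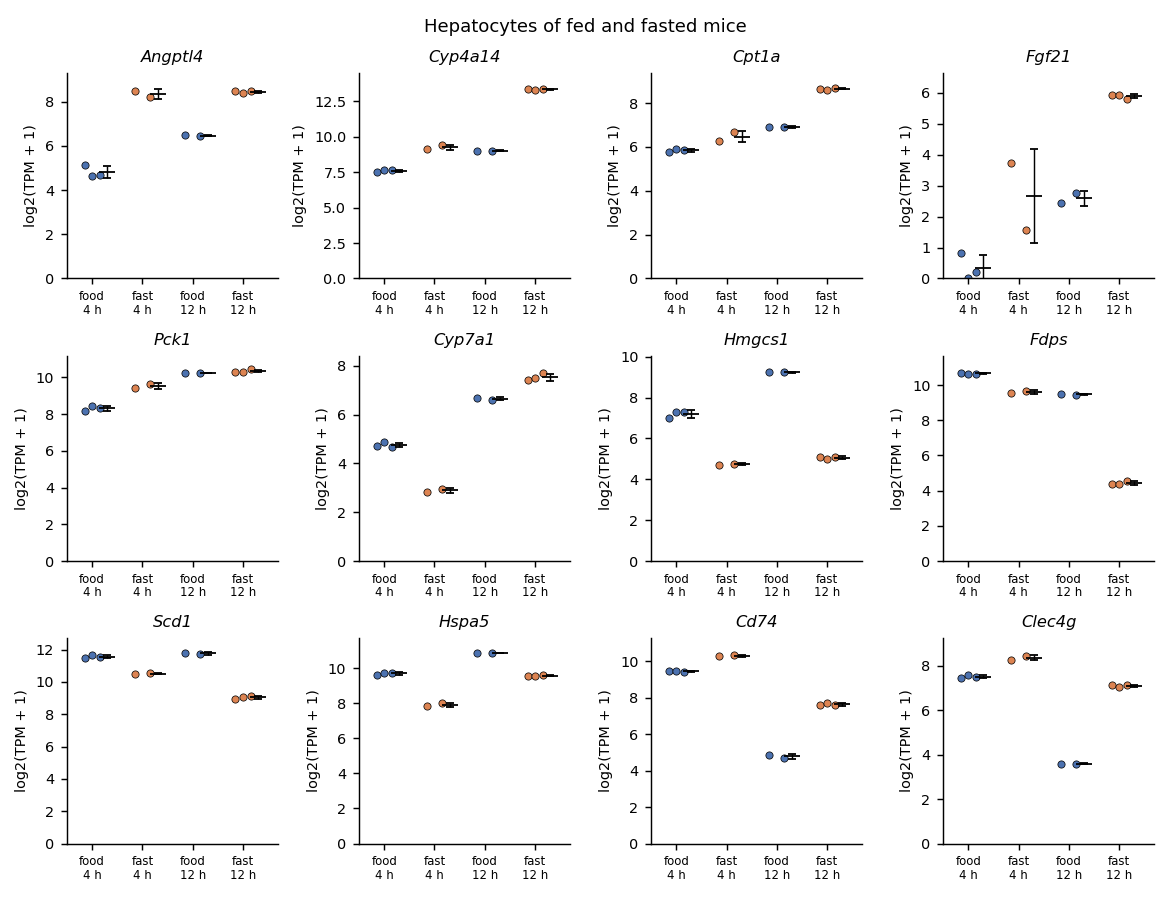
Expression of 12 genes in fed and fasted hepatocytes at 4 h and 12 h, as log2(TPM + 1) on the vertical axis, with each point 1 library and each dash with its bar the mean and SD of a group. Cyp4a14 rose with fasting at both times (log2 fold change 1.68 at 4 h and 4.34 at 12 h), and Fdps fell (-1.05 and -5.03).

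The second question was what 12 h without food does to hepatocytes. Genes of fatty acid oxidation rose again. Cyp4a14 rose from 511 ± 9.55 to 10412 ± 138 TPM (SD, n = 2 fed and 3 fasted; log2 fold change 4.34, SE 0.07, adjusted p = 4.1e-10), and Cpt1a rose from 119.7 ± 2.35 to 403 ± 9.21 TPM (log2 fold change 1.74, SE 0.11, adjusted p = 1.6e-06). Fgf21 rose from 5.07 ± 1.00 to 58.2 ± 2.74 TPM (log2 fold change 3.29, SE 0.52, adjusted p = 7.9e-04). The largest rise among genes with separate groups and a mean of at least 10 TPM was in Cidec, a lipid droplet protein, at 205 ± 8.68 TPM in fasted and 0.519 ± 0.0094 TPM in fed libraries (log2 fold change 7.08, SE 0.17, adjusted p = 6.0e-09). Apoa4, an apolipoprotein, rose from 248 ± 0.383 to 11002 ± 178 TPM (log2 fold change 5.46, SE 0.08, adjusted p = 3.0e-10). Of 42 PPARA targets and fatty acid oxidation genes 32 rose and 3 fell (32 rose and 3 fell over the list alone), with a median 0.68 above that of all genes (camera adjusted p = 4.8e-11, and adjusted p = 0.082 with an estimated correlation). The gluconeogenic genes Pck1 (log2 fold change 0.13, SE 0.09, adjusted p = 0.29) and G6pc (log2 fold change 0.02, SE 0.06, adjusted p = 0.82) and Ppara itself (log2 fold change -0.04, SE 0.14, adjusted p = 0.85) did not pass. G6pc was called higher after quantile normalization (0.21, adjusted p = 0.020; range over its alternatives 0.020 to 0.931).

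All 24 measured cholesterol synthesis genes fell at 12 h. Fdps, which makes farnesyl diphosphate, fell from 711 ± 17.6 to 20.8 ± 1.78 TPM (SD, n = 2 fed and 3 fasted; log2 fold change -5.03, SE 0.08, adjusted p = 3.0e-10). Hmgcs1 fell from 605 ± 4.99 to 32.5 ± 1.24 TPM (log2 fold change -4.18, SE 0.11, adjusted p = 6.0e-09). The median of the list was -2.83 relative to all genes (24 fell over the list alone; camera adjusted p = 4.2e-19, and adjusted p = 0.017 with an estimated correlation), and the call held with the estimated correlation. Scd1 fell from 3479 ± 174 to 528 ± 33.6 TPM (log2 fold change -2.72, SE 0.07, adjusted p = 6.4e-09). Of 16 lipogenesis genes 9 fell and 1 rose (3 rose and 9 fell over the list alone; camera adjusted p = 5.5e-04, and adjusted p = 0.20 with an estimated correlation). Cyp7a1, which fell at 4 h, rose from 99.7 ± 4.59 to 185 ± 19.0 TPM (log2 fold change 0.88, SE 0.12, adjusted p = 2.8e-04). Car3, a carbonic anhydrase of hepatocytes, had the largest fall by the same rule (3832 ± 185 TPM in fed and 23.2 ± 1.74 TPM in fasted libraries; log2 fold change -7.31, SE 0.09, adjusted p = 1.2e-10). The growth hormone receptor Ghr fell (log2 fold change -1.78, SE 0.13, adjusted p = 5.5e-06). Of 15 growth hormone responsive and sex-biased genes, 9 fell and 1 rose (1 rose and 9 fell over the list alone; camera adjusted p = 4.1e-05, and adjusted p = 0.021 with an estimated correlation). Of 21 heat shock and unfolded protein response genes 17 fell and 1 rose (1 rose and 17 fell over the list alone; camera adjusted p = 2.0e-08, and adjusted p = 0.018 with an estimated correlation). Hspa5 fell from 1887 ± 15.7 to 768 ± 23.1 TPM (log2 fold change -1.30, SE 0.07, adjusted p = 4.3e-07). Immediate early genes moved the other way from 4 h, as with Ier2 (log2 fold change -1.81, SE 0.09, adjusted p = 3.6e-07). Of 16 such genes 10 fell and 3 rose (3 rose and 11 fell over the list alone; camera adjusted p = 3.5e-04, and adjusted p = 0.23 with an estimated correlation). For the heat shock and immediate early lists the fed 12 h libraries stood high. The mean log2 value of the heat shock list was 6.80 to 6.85 in fasted 12 h libraries. It was 7.77 and 7.79 in fed 12 h and 6.82 to 6.87 in fed 4 h libraries. For the immediate early list it was 4.82 to 4.92, 5.58 and 5.55, and 4.82 to 4.97, in the same order. Why the fed 12 h libraries stood high was not tested.

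Markers of macrophages, endothelium and erythroid cells stood low in the fed 12 h libraries. C1qb was at 13.8 ± 0.955 TPM (SD, n = 2) in fed and 111 ± 1.97 TPM (SD, n = 3) in fasted libraries (log2 fold change 2.92, SE 0.08, adjusted p = 1.1e-08). Clec4g was at 10.99 ± 0.211 and 137 ± 3.81 TPM (log2 fold change 3.52, SE 0.08, adjusted p = 4.8e-09). All 14 Kupffer cell and macrophage markers rose (14 over the list alone; camera adjusted p = 1.1e-10, and adjusted p = 0.018 with an estimated correlation). So did all 13 endothelial markers (13 over the list alone; camera adjusted p = 4.8e-11, and adjusted p = 0.017 with an estimated correlation). Of 7 erythroid markers 5 rose and 1 fell (5 rose and 1 fell over the list alone), with a median 3.11 above all genes (camera adjusted p = 0.045, and adjusted p = 0.39 with an estimated correlation). Cd74 rose from 26.6 ± 2.36 to 199 ± 9.04 TPM (log2 fold change 2.86, SE 0.07, adjusted p = 6.0e-09). Of 8 MHC class II genes 7 rose (7 rose and 0 fell over the list alone; camera adjusted p = 7.3e-05, and adjusted p = 0.084 with an estimated correlation). The summed Kupffer cell markers were 235 and 241 TPM in fed and 902, 898 and 908 TPM in fasted 12 h libraries, below all 4 h libraries. Between fed hepatocytes at 12 h and 4 h, Cd74 fell by 4.68 and Clec4g by 3.93 on the log2 scale (adjusted p = 9.1e-10 and 3.8e-09). There the 14 Kupffer cell markers had a median -3.67 relative to all genes (1 rose and 13 fell, 1 rose and 13 fell over the list alone; camera adjusted p = 2.2e-09, and adjusted p = 0.044 with an estimated correlation). The 7 erythroid markers were at -6.98 (1 rose and 5 fell, 1 rose and 5 fell over the list alone; camera adjusted p = 0.0070, and adjusted p = 0.29 with an estimated correlation). In that comparison 5301 of 8966 genes changed, 2988 up and 2313 down, and the split was 2495 up and 2757 down after quantile normalization, 2376 up and 3106 down after centring on the median and 2299 up and 2907 down after a length trend was removed. With fasting at 12 h, 3609 of 8966 genes changed, 2099 up and 1510 down. The split was closer to even under other scalings: 1929 up and 1939 down after quantile normalization, 1884 and 1842 after centring on the median, and 1850 and 1756 after a length trend was removed. The groups did not overlap for 71.4% of genes, against 20% by chance.

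Whether the difference between fasted and fed libraries was another at 12 h than at 4 h was tested as an interaction over all 10 hepatocyte libraries. The labels do not say whether cells of the 2 times were isolated together, so time and isolation are not separated here. Cyp4a14 rose more at 12 h (interaction log2 fold change 2.66, adjusted p = 2.8e-07), as did Cpt1a (1.12, adjusted p = 6.9e-04). Fdps (-3.98, adjusted p = 6.0e-08) fell more at 12 h. Angptl4 (-1.54, adjusted p = 6.5e-04) and Pck1 (-1.07, adjusted p = 2.9e-04) rose more at 4 h. Fgf21 was not shown to differ (0.98, adjusted p = 0.35). Of 24 cholesterol synthesis genes 21 had a lower interaction and none a higher one (0 higher and 21 lower over the list alone; camera adjusted p = 7.7e-19, and adjusted p = 0.033 with an estimated correlation). Kupffer cell markers had 13 of 14 higher and none lower (13 higher and 0 lower over the list alone; camera adjusted p = 1.3e-08, and adjusted p = 0.041 with an estimated correlation), and endothelial markers 13 of 13 (13 higher and 0 lower over the list alone; camera adjusted p = 1.3e-08, and adjusted p = 0.034 with an estimated correlation). The interaction passed for 2750 of 8966 genes, 2084 up and 666 down, at a median of 0.33, so each interaction above is 0.33 lower relative to the median gene. The split was 1326 up and 1054 down after quantile normalization, 1439 and 975 after centring on the median, and 1136 and 1115 after a length trend was removed. Without fed 12 h library 1 the count was 1711 and without fed 12 h library 2 it was 1603. Across 8966 genes, which are not independent replicates, the log2 fold changes at 4 h and 12 h had a Pearson correlation of 0.430.

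The third question was what 4 h without food does to monocytes of the bone marrow. Genes that glucocorticoids switch on rose. Nfkbia, the inhibitor of NF-kB, rose from 166 ± 16.3 to 341 ± 34.8 TPM (SD, n = 4 and 4; log2 fold change 1.04, SE 0.10, adjusted p = 0.0019). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, rose from 361 ± 73.6 to 737 ± 79.0 TPM (log2 fold change 1.04, SE 0.13, adjusted p = 0.0055). Fpr2, a receptor for formylated peptides, rose from 11.5 ± 1.36 to 40.7 ± 9.68 TPM (log2 fold change 1.71, SE 0.17, adjusted p = 0.0019). The proteoglycan Vcan rose from 19.0 ± 4.30 to 52.9 ± 8.78 TPM (log2 fold change 1.44, SE 0.17, adjusted p = 0.0042). Cd24a fell from 79.5 ± 7.91 to 43.4 ± 3.80 TPM (log2 fold change -0.86, SE 0.10, adjusted p = 0.0042). The cholesterol synthesis gene Fdps fell from 159 ± 11.03 to 94.8 ± 9.58 TPM (log2 fold change -0.74, SE 0.09, adjusted p = 0.0053). The fed and fasted libraries did not overlap for any of these genes. The clock gene Per1 rose (log2 fold change 1.57, SE 0.23, adjusted p = 0.016), a call that ended without fasted library 3 (adjusted p = 0.066) and without fed library 3 (0.0598), with a range over its alternatives of 0.0067 to 0.066. Of 16 glucocorticoid response genes 8 rose and none fell (11 rose and 0 fell over the list alone). The list had a median 1.06 above that of all genes (camera adjusted p = 1.6e-16, and adjusted p = 0.029 with an estimated correlation) and was the 1 list call here that held with the estimated correlation. Of 20 cholesterol synthesis genes 4 fell (0 rose and 12 fell over the list alone; camera adjusted p = 1.8e-08, and adjusted p = 0.075 with an estimated correlation). Of 23 classical monocyte genes 3 rose (5 rose and 0 fell over the list alone; camera adjusted p = 6.1e-10, and adjusted p = 0.053 with an estimated correlation). Ribosomal protein genes stood 0.31 above all genes, with none of 42 called singly (1 rose and 1 fell over the list alone; camera adjusted p = 4.9e-14, and adjusted p = 0.54 with an estimated correlation). Cell cycle genes stood at -0.22, with none of 40 called singly (1 rose and 28 fell over the list alone; camera adjusted p = 2.2e-10, and adjusted p = 0.42 with an estimated correlation).

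Some well-known genes of monocyte traffic did not pass at 4 h. Ccr2, the chemokine receptor needed for monocytes to leave the marrow, was at 1939.7 ± 227 TPM (SD, n = 4) in fasted and 2059 ± 57.7 TPM (SD, n = 4) in fed monocytes (log2 fold change -0.09, SE 0.09, adjusted p = 0.61). Ly6c2, the surface antigen of inflammatory monocytes, was at 6066 ± 981 and 5512 ± 1010.1 TPM (log2 fold change 0.14, SE 0.15, adjusted p = 0.63). Cx3cr1 was at 162 ± 22.9 and 177 ± 32.0 TPM (log2 fold change -0.12, SE 0.14, adjusted p = 0.65). Cxcr4, which holds cells in the marrow, was at 169 ± 34.3 and 137 ± 17.6 TPM (log2 fold change 0.29, SE 0.14, adjusted p = 0.35). Of 19 chemokine receptor and adhesion genes 2 rose (6 rose and 4 fell over the list alone), and the list did not pass (camera adjusted p = 0.18, and adjusted p = 0.78 with an estimated correlation). Of 5 lists of markers of other cells, those of dendritic cells, progenitors and microglia did not pass, and 2 passed camera at the preset correlation but not with an estimated one. The 6 erythroid markers had a median 1.21 above all genes (0 changed singly, 3 rose and 0 fell over the list alone; camera adjusted p = 1.4e-04, and adjusted p = 0.053 with an estimated correlation). The 7 neutrophil markers had a median 0.32 above all genes (0 changed singly, 3 rose and 0 fell over the list alone; camera adjusted p = 2.4e-04, and adjusted p = 0.053 with an estimated correlation). In all, 40 of 9428 genes changed, 25 up and 15 down, and the split was 23 up and 8 down after centring on the median and 29 up and 8 down after a length trend was removed. The groups did not overlap for 8.81% of genes, against 2.86% by chance. The count was 145 without fasted library 1, 24 without fasted library 2, 18 without fasted library 3 and 26 without fasted library 4; it was 14 without fed library 2 and 15 without fed library 3.

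After 17 h without food, monocytes from the marrow differed from fed ones in most genes. Thbs1, a matrix glycoprotein, rose from 0.535 ± 0.275 to 163 ± 71.3 TPM (SD, n = 3 fed and 4 fasted; log2 fold change 6.60, SE 0.39, adjusted p = 2.0e-07), 5.42 above the median gene. Vcan rose from 3.10 ± 0.879 to 78.8 ± 18.4 TPM (log2 fold change 4.27, SE 0.20, adjusted p = 1.0e-07; 3.09 above the median gene). Chil3, a secreted protein of monocytes, rose from 3023 ± 432 to 38634 ± 6372 TPM (log2 fold change 3.67, SE 0.15, adjusted p = 7.2e-08; 2.49 above). The glucocorticoid target Fkbp5 rose from 5.75 ± 1.33 to 70.2 ± 7.499 TPM (log2 fold change 3.41, SE 0.15, adjusted p = 8.5e-08; 2.23 above). Ly6c2 fell from 12087 ± 766 to 5225 ± 328 TPM (log2 fold change -1.21, SE 0.09, adjusted p = 6.1e-07; -2.39 relative to the median gene). S100a4, a calcium-binding protein, fell from 1119.7 ± 177 to 83.7 ± 82.1 TPM (log2 fold change -4.28, SE 0.81, adjusted p = 0.0019). Ccr2 rose from 526 ± 34.7 to 1966 ± 178 TPM (log2 fold change 1.90, SE 0.10, adjusted p = 1.3e-07), 0.72 above the median gene, and by 0.19 with no call once a length trend was removed (adjusted p = 0.15; range over its alternatives 1.2e-07 to 0.15). Cx3cr1 rose from 41.6 ± 7.505 to 255 ± 19.1 TPM (log2 fold change 2.60, SE 0.13, adjusted p = 1.1e-07; 1.42 above the median gene). No fed library overlapped a fasted one for these genes. For Ccr2 and Ly6c2 the fasted 17 h means lay near the fed 4 h means given above. Their fed 17 h means lay far from both. For Vcan the fasted 17 h mean lay above the fed 4 h mean, and the fed 17 h mean below it. The 2 experiments were normalized separately.

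Genes of translation and respiration stood lower in fasted than in fed 17 h monocytes, but the fed 17 h libraries were high among fed marrow libraries. Summed TPM of the ribosomal protein list was 12420 to 15950 in fasted and 33760 to 35810 in fed 17 h libraries. In fed 4 h libraries it was 14880 to 19090, and in C57BL/6 libraries 8839 to 10890. Oxidative phosphorylation genes summed to 8891 to 10300, 22690 to 26090, 8412 to 9666 and 7760 to 8590 TPM in the same order. The ribosomal protein gene Rplp2 fell from 499 ± 86.4 to 106 ± 10.9 TPM (SD, n = 3 fed and 4 fasted; log2 fold change -2.22, SE 0.13, adjusted p = 2.2e-07). Ndufb3, of respiratory complex I, fell from 320.1 ± 4.10 to 78.5 ± 4.997 TPM (log2 fold change -2.02, SE 0.09, adjusted p = 7.7e-08). Of 41 ribosomal protein genes 36 fell and 2 rose (2 rose and 36 fell over the list alone; camera adjusted p = 7.0e-29, and adjusted p = 0.43 with an estimated correlation). Of 45 oxidative phosphorylation genes 31 fell and 9 rose (9 rose and 31 fell over the list alone; camera adjusted p = 3.2e-20, and adjusted p = 0.43 with an estimated correlation). All 19 chemokine receptor and adhesion genes rose, where 6888 of all 9134 genes did (19 over the list alone, camera adjusted p = 0.029, and adjusted p = 0.67 with an estimated correlation). Their summed TPM was 7000 to 7285 in fasted and 2003 to 2292 in fed 17 h libraries. It was 7237 to 7417 in fed 4 h and 7792 to 8278 in C57BL/6 libraries, so only the fed 17 h libraries were low among these. In all, 8171 of 9134 genes changed, 6888 up and 1283 down, at a median log2 fold change of 1.18. The split was 3860 up and 2942 down after quantile normalization, 3737 and 3323 after centring on the median, and 3293 and 3183 after a length trend was removed. Of the 8171 genes, 1900, 2051 and 2126 had the other sign under these 3 settings. The groups did not overlap for 88.3% of genes, against 5.71% by chance. The fed 17 h libraries stood apart from all other marrow libraries: their mean correlation with fed marrow libraries of the other experiments was 0.733 to 0.763, against 0.940 to 0.955 for fasted 17 h libraries. Their median gene was at 17.2, 15.7 and 15.5 TPM, against 34.5 to 37.1 TPM in fasted libraries. Without fasted library 1, 5 gene lists passed in place of 8. Among lists of other cells, the 11 progenitor markers had a median -1.13 relative to all genes (5 rose and 5 fell; camera adjusted p = 0.040, and adjusted p = 0.67 with an estimated correlation). That call held in 5 of 7 fits without 1 library (highest adjusted p = 0.0534) and ended after quantile normalization (0.33) and once a length trend was removed (0.13). The 12 neutrophil-like granule genes were at -1.26 (6 rose and 6 fell; camera adjusted p = 0.047, and adjusted p = 0.67 with an estimated correlation), a call that held in 4 of 7 fits (highest adjusted p = 0.0575) and ended after quantile normalization (0.87) and once a length trend was removed (0.53). The 5 neutrophil markers went the other way, at a median 1.35 above all genes (4 rose and 1 fell; camera adjusted p = 0.79, and adjusted p = 0.88 with an estimated correlation), and did not pass. Their summed TPM was 1026 to 1499 in fasted and 231 to 277 in fed 17 h libraries. Erythroid markers summed to 964 TPM in fasted library 4 and to 72.5 to 110 TPM in the other fasted libraries.

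**Figure D2:**
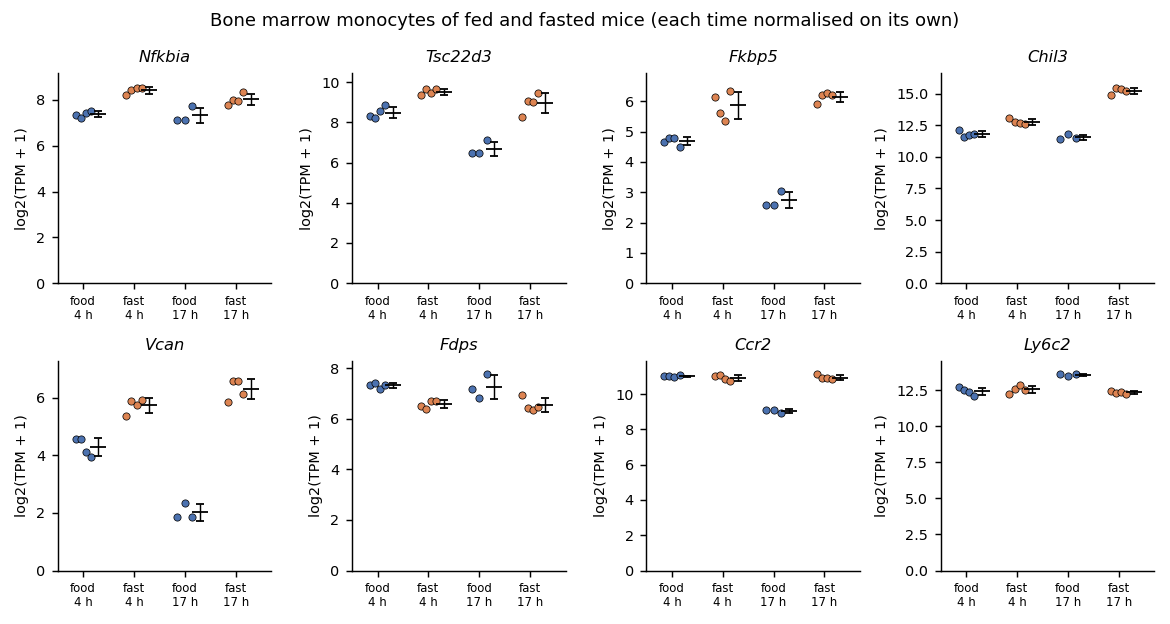
Expression of 8 genes in bone marrow monocytes of fed and fasted mice at 4 h and 17 h, as log2(TPM + 1) on the vertical axis, with each point 1 library and each dash with its bar the mean and SD of a group; the 2 times were normalized separately. Tsc22d3 rose at 4 h (log2 fold change 1.04), and Ly6c2 was lower in fasted than in fed libraries at 17 h (-1.21).

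The fasting effect at 17 h was set against that at 4 h, although the 2 times come from 2 experiments, so time cannot be told from experiment. Fkbp5, which rose at both times, had an interaction log2 fold change of 2.24 (adjusted p = 4.3e-07), 0.97 above the median gene. Vcan had 2.83 (adjusted p = 5.4e-08; 1.56 above), and Chil3 2.72 (adjusted p = 4.3e-09; 1.44 above). For Ccr2 the interaction was 1.99 (adjusted p = 7.3e-10), and 0.15 with no call after a length trend was removed (adjusted p = 0.40). For Ly6c2 it was -1.35 (adjusted p = 2.8e-06), and -0.16 with no call after quantile normalization (adjusted p = 0.42). The interaction passed for 7782 of 8844 genes, 6638 up and 1144 down, at a median of 1.27. The split was 3517 up and 2489 down after quantile normalization, 3489 and 2936 after centring on the median, and 2896 and 2869 after a length trend was removed. Of 41 ribosomal protein genes 35 had a lower and 3 a higher interaction (3 higher and 36 lower over the list alone; camera adjusted p = 6.2e-29, and adjusted p = 0.27 with an estimated correlation). Of the gene lists 4 passed, and 8 passed without fasted 17 h library 4, 7 without fasted 4 h library 2 and 7 without fed 17 h library 2. Across 8843 genes, which are not independent replicates, the 4 h and 17 h fold changes had a Pearson correlation of -0.364.

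In CCR2-/- monocytes, the targeted gene Ccr2 was at 64.7, 62.3 and 60.8 TPM, against 2449, 2622 and 2338 TPM in C57BL/6 monocytes (log2 fold change -5.28, SE 0.07, adjusted p = 4.5e-09). The lipid carrier Apoe rose from 760.2 ± 94.2 to 1884 ± 135 TPM (SD, n = 3 and 3; log2 fold change 1.31, SE 0.10, adjusted p = 0.0013). The dipeptidase Dpep2 rose from 54.8 ± 5.17 to 124 ± 12.6 TPM (log2 fold change 1.16, SE 0.10, adjusted p = 0.0031). Ace, a gene of non-classical monocytes, fell from 33.6 ± 3.94 to 4.83 ± 1.68 TPM (log2 fold change -2.60, SE 0.20, adjusted p = 0.0013). The muscle-type enolase Eno3 fell from 15.4 ± 0.7 to 5.16 ± 0.553 TPM (log2 fold change -1.41, SE 0.12, adjusted p = 0.0024). Ly6c2 (log2 fold change 0.23, SE 0.12, adjusted p = 0.27), Cx3cr1 (log2 fold change -0.01, SE 0.12, adjusted p = 0.96) and Cxcr4 (log2 fold change 0.20, SE 0.13, adjusted p = 0.36) did not pass. Of 17 non-classical monocyte genes 7 fell and none rose (0 rose and 10 fell over the list alone; camera adjusted p = 4.9e-04, and adjusted p = 0.54 with an estimated correlation). Of 10 MHC class II genes 4 rose (6 rose and 0 fell over the list alone; camera adjusted p = 3.8e-05, and adjusted p = 0.54 with an estimated correlation). Of 40 interferon-stimulated genes none passed singly (16 rose and 0 fell over the list alone). The median of the list was 0.46 above all genes (camera adjusted p = 4.5e-13, and adjusted p = 0.54 with an estimated correlation).

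Immediate early genes, which also rise while cells are isolated, stood high in the C57BL/6 libraries of this experiment. Egr1 was at 261, 106 and 62.3 TPM in C57BL/6 and at 0.715, 0.432 and 0.367 TPM in CCR2-/- monocytes (log2 fold change -6.34, SE 0.43, adjusted p = 0.0010). The summed TPM of the immediate early list was 5957, 3573 and 2587 in C57BL/6 and 1352, 1286 and 1319 in CCR2-/- libraries, and 548 to 1907 in the other marrow libraries. Of 16 such genes 11 fell (0 rose and 14 fell over the list alone; camera adjusted p = 1.4e-10, and adjusted p = 0.54 with an estimated correlation). Fos fell from 682 ± 468 to 74.6 ± 16.1 TPM (SD, n = 3 and 3; log2 fold change -2.99, SE 0.41, adjusted p = 0.028), a call that ended without C57BL/6 library 2 (adjusted p = 0.0504) and without CCR2-/- library 1, 2 or 3 (0.0651, 0.163 and 0.122), with a range over its alternatives of 0.0076 to 0.163. In all, 403 of 9210 genes changed, 59 up and 344 down, and the split was 94 up and 222 down after quantile normalization, 123 and 239 after centring on the median, and 104 and 309 after a length trend was removed. Without a trend in limma only 48 genes were called, 17 up and 31 down. The groups did not overlap for 33.3% of genes, against 10% by chance. The count was 22 without C57BL/6 library 1, 28 without C57BL/6 library 2 and 750 without C57BL/6 library 3. It was 1060 without CCR2-/- library 1, 12 without CCR2-/- library 2 and 11 without CCR2-/- library 3.

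**Figure D3:**
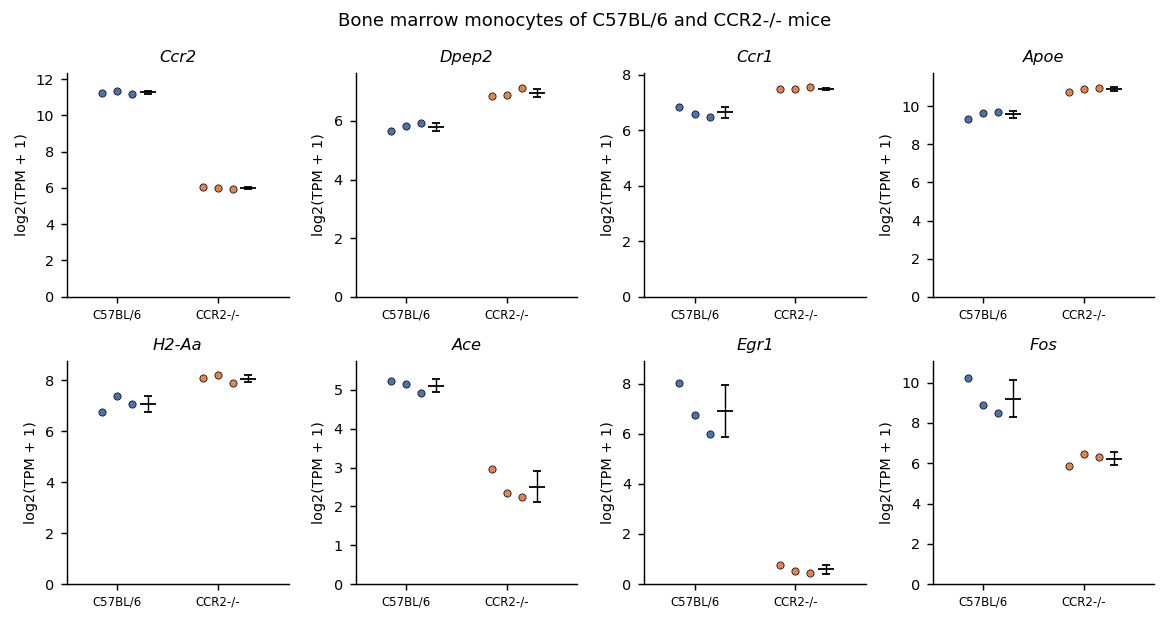
Expression of 8 genes in bone marrow monocytes of C57BL/6 and CCR2-/- mice, as log2(TPM + 1) on the vertical axis, with each point 1 library and each dash with its bar the mean and SD of a group. Ccr2 fell (log2 fold change -5.28) while Apoe rose (1.31).

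The last question was how 4 weeks of fasting cycles alter monocytes in the spinal cord of mice with EAE. Genes of inflammation and of the interferon response fell. Ptgs2, the enzyme of prostaglandin synthesis, fell from 113 ± 49.8 to 4.29 ± 1.00 TPM (SD, n = 4 and 4; log2 fold change -4.29, SE 0.42, adjusted p = 0.0023). Nfkbiz, a nuclear regulator of NF-kB, fell from 590.2 ± 341 to 51.4 ± 6.87 TPM (log2 fold change -3.29, SE 0.41, adjusted p = 0.0082). The antiviral gene Oas3 fell from 47.6 ± 12.6 to 3.56 ± 0.759 TPM (log2 fold change -3.38, SE 0.29, adjusted p = 8.2e-04). Ddx58, a sensor of viral RNA, fell from 28.5 ± 4.87 to 5.72 ± 1.37 TPM (log2 fold change -2.14, SE 0.26, adjusted p = 0.0074). Mrap, an accessory protein of melanocortin receptors, rose from 0.199 ± 0.0938 to 19.8 ± 2.89 TPM (log2 fold change 4.11, SE 0.25, adjusted p = 1.7e-04). Flt3, a growth factor receptor, rose from 6.96 ± 2.64 to 97.5 ± 17.1 TPM (log2 fold change 3.67, SE 0.29, adjusted p = 6.2e-04). The sulfotransferase Sult1a1, a glucocorticoid target, rose from 2.42 ± 0.31 to 50.5 ± 19.3 TPM (log2 fold change 3.85, SE 0.29, adjusted p = 6.2e-04). The groups did not overlap for any of these genes. The median gene rose by 0.26, so each log2 fold change here is 0.26 lower relative to it. Of 37 interferon-stimulated genes 16 fell and none rose (0 rose and 26 fell over the list alone), and their median was -1.95 relative to all genes (camera adjusted p = 5.1e-33, and adjusted p = 0.11 with an estimated correlation). Of 17 inflammatory cytokines and mediators 7 fell (1 rose and 10 fell over the list alone; camera adjusted p = 1.5e-09, and adjusted p = 0.11 with an estimated correlation). Of 20 cholesterol synthesis genes 3 fell (0 rose and 9 fell over the list alone; camera adjusted p = 4.9e-08, and adjusted p = 0.11 with an estimated correlation). Of 43 ribosomal protein genes 17 rose (42 rose and 0 fell over the list alone; camera adjusted p = 1.4e-21, and adjusted p = 0.26 with an estimated correlation). The glucocorticoid response list did not pass (5 of 15 rose, 6 rose and 1 fell over the list alone; camera adjusted p = 0.053, and adjusted p = 0.23 with an estimated correlation). Of 6 lists of markers of other cells, those of macrophages, dendritic cells and progenitors did not pass. Those of microglia, erythroid cells and neutrophils passed camera at the preset correlation but not with an estimated one, and none of their genes passed singly. The 7 microglia markers had a median -1.11 relative to all genes (0 rose and 3 fell over the list alone; camera adjusted p = 0.0011, and adjusted p = 0.13 with an estimated correlation). The 5 erythroid markers were at -1.82 (0 rose and 0 fell over the list alone; camera adjusted p = 7.6e-04, and adjusted p = 0.32 with an estimated correlation).

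Chemokine receptor genes varied widely between spinal cord libraries. Ccr2 was at 49.8, 57.8, 889 and 856 TPM in the fed and at 213, 787, 287 and 463 TPM in the fasted libraries (log2 fold change 0.83, SE 0.97, adjusted p = 0.63). Cx3cr1 was at 9.29, 60.5, 59.9 and 49.1 TPM in the fed and at 5.73, 0.895, 1.00 and 11.6 TPM in the fasted libraries (log2 fold change -3.14, SE 0.75, adjusted p = 0.059). It was called lower after quantile normalization (adjusted p = 0.021) and without fed library 1 (adjusted p = 0.0263), with a range over its alternatives of 0.0209 to 0.217. Ly6c2 (log2 fold change 0.66, SE 0.31, adjusted p = 0.26) and Ccl2 (log2 fold change -0.85, SE 0.64, adjusted p = 0.46) did not pass. Neutrophil markers were high in fed libraries 1 and 2: the summed TPM of 12 neutrophil markers was 171700 and 176700 there, 5448 and 3221 in fed libraries 3 and 4, and 11310 to 15450 in fasted libraries. None of these markers passed singly (1 rose and 4 fell over the list alone). The list fell (camera adjusted p = 4.4e-04, and adjusted p = 0.50 with an estimated correlation), a call that ended without fed library 1 (camera adjusted p = 0.0836), after quantile normalization (0.068) and once a length trend was removed (0.065). Fasted library 1 stood apart in another way. Lars2 was its top gene at 80632 TPM, and its mitochondrially encoded genes summed to 42140 TPM, against 6989 to 9451 TPM in the other fasted libraries. The immediate early list was high in fed libraries, at 21410 to 23700 TPM in sum against 7661 to 14670 TPM in fasted ones (3 of 19 genes fell, 0 rose and 10 fell over the list alone; camera adjusted p = 1.8e-11, and adjusted p = 0.11 with an estimated correlation). In all, 221 of 9079 genes changed, 143 up and 78 down. The split was 493 up and 290 down after quantile normalization, 470 and 217 after centring on the median, and 362 and 270 after a length trend was removed. No overlap of the groups was seen for 15.2% of genes, against 2.86% by chance. With fed libraries 3 and 4 as the only fed ones, 774 genes changed, 293 up and 481 down. The count was 90 without fed library 1, 85 without fed library 2 and 745 without fed library 3. It was 64, 29, 22 and 40 without fasted library 1, 2, 3 and 4.

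**Figure D4:**
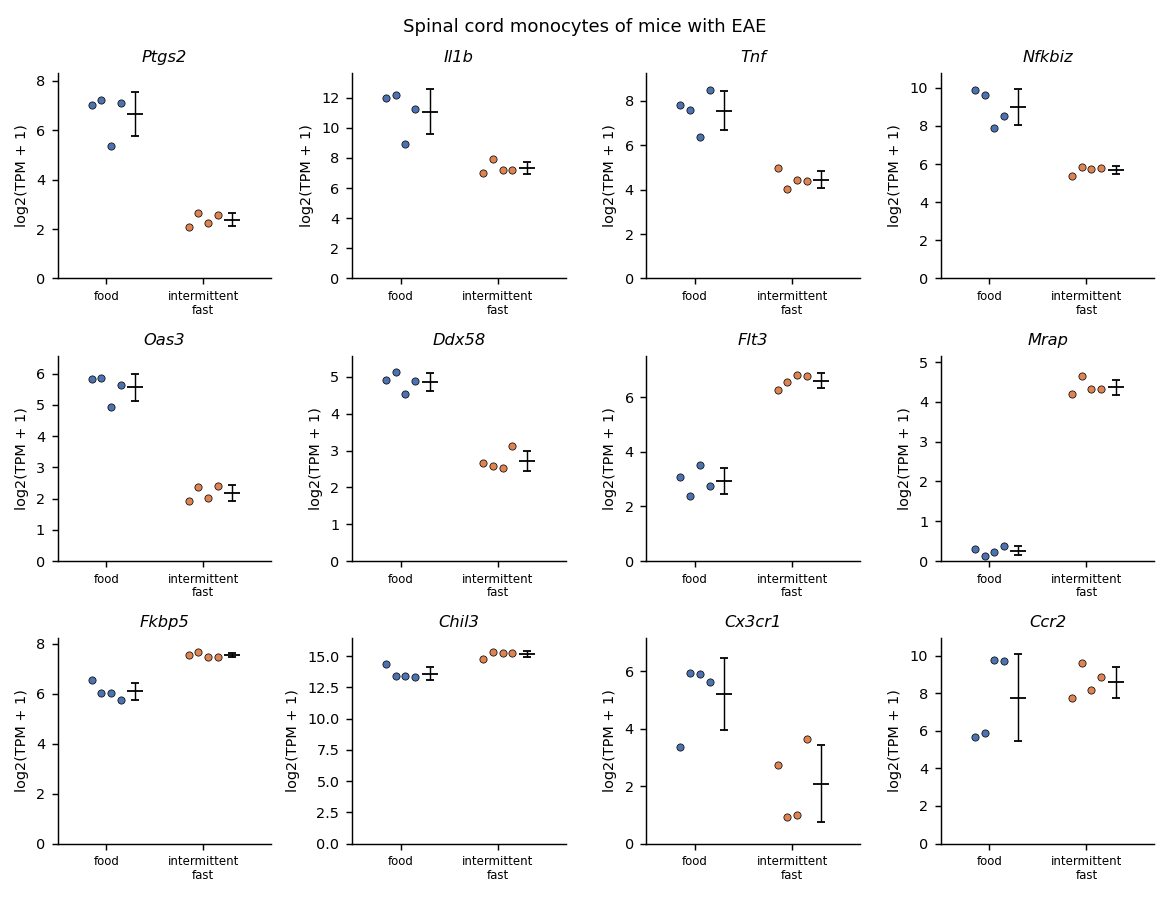
Expression of 12 genes in spinal cord monocytes of fed and intermittently fasted mice with EAE, as log2(TPM + 1) on the vertical axis, with each point 1 library and each dash with its bar the mean and SD of a group. Ptgs2 fell (log2 fold change -4.29) and Mrap rose (4.11), while Ccr2 spread widely among fed libraries.

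**Figure D5:**
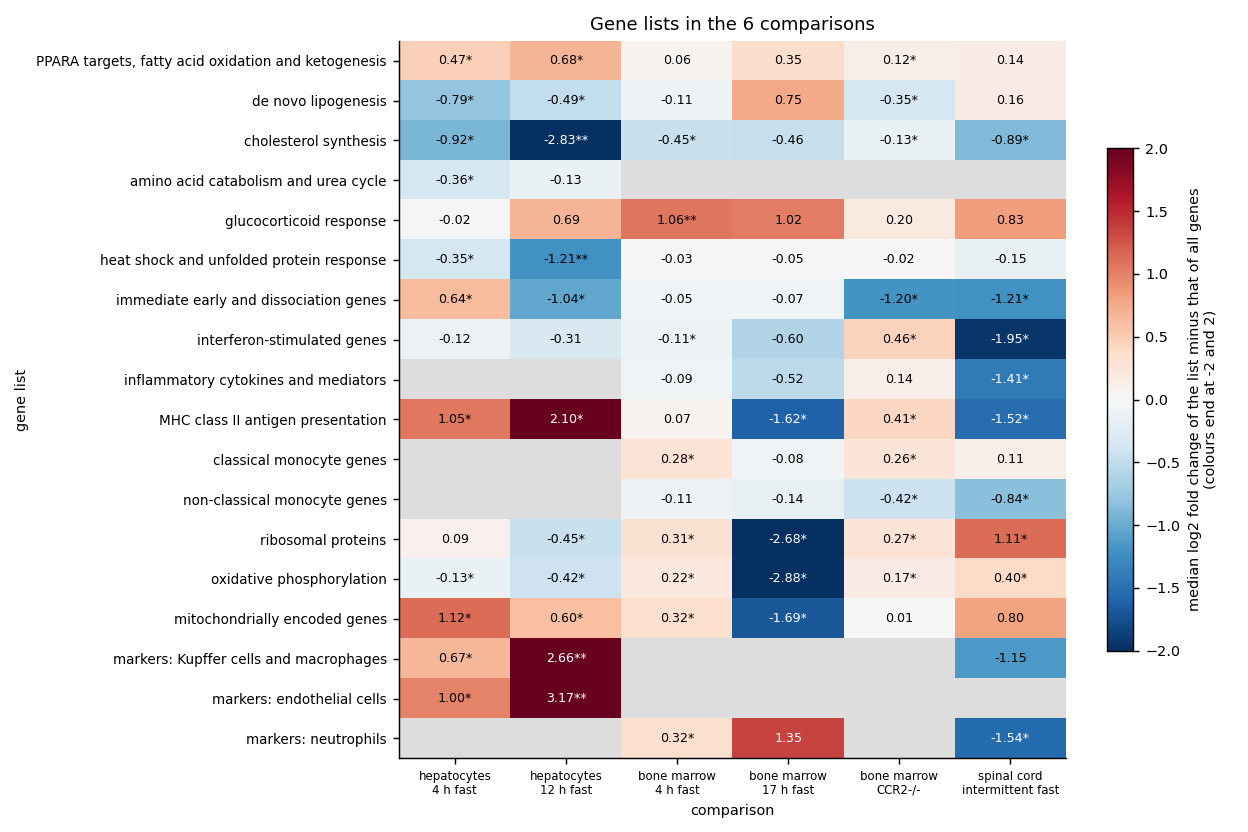
Median log2 fold change of 18 gene lists minus that of all genes, with lists on the vertical axis and the 6 comparisons on the horizontal axis, in color from blue (lower) to red (higher); 1 star marks a list that passed camera, 2 stars a list that also passed with an estimated correlation, and gray a list not tested. Cholesterol synthesis fell most in hepatocytes at 12 h (-2.83), and interferon-stimulated genes in spinal cord monocytes (-1.95).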

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

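The tests of transcript length, of fed libraries standing apart and of the closest neighbors of Ccr2 were chosen only after the results were seen.

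Some values lay far from the rest of their group by Dixon's test, which picks about 1 in 20 groups by chance. Of 199 gene values and 10 library measures tested, 8 and 2 did. In fed marrow monocytes at 4 h, the mitochondrial import gene Timm8b was at 3.41 TPM in library 1 and listed at 0 in the others. At 17 h, fasted library 4 had Csf1r at 529 TPM (others 365 to 378) and Nr4a1 at 34.6 TPM (others 29.9 to 30.3), and fasted library 3 had Ndufb2 at 42.4 TPM (others 8.87 to 11.9). In spinal cord, fed library 1 had Chil3 at 20800 TPM (others 10100 to 10900). Fasted library 1 had Btg2 at 175 TPM (others 285 to 305) and Rnase2a at 25.1 TPM (others 6.95 to 9.56), and fasted library 4 had Pmaip1 at 17.4 TPM (others 8.61 to 10). Among library measures, the median log2 value of fed 4 h marrow library 1 was 5.27 (others 5.31 to 5.32), and the correlation of values with transcript length in fasted spinal cord library 2 was 0.0473 (others -0.178 to -0.14).

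In both cell types the difference between fasted and fed libraries was not the same at the 2 times, by the interaction in limma. No test separates fasting from what else sets the fed libraries of the later times apart. In hepatocytes 2750 genes differed, among them Ppara (-0.62), Angptl4 (-1.54), Pck1 (-1.07), G6pc (-0.34) and Srebf1 (-1.29), lower at 12 h than at 4 h in that difference, and Cpt1a (1.12) and Cyp7a1 (2.75), higher. The call for Ppara (adjusted p = 0.040) ended after quantile normalization (adjusted p = 0.050). Without fed 12 h library 1 or 2 the count was 1711 or 1603. In marrow monocytes 7782 genes differed, at a median of 1.27, among them Ccr2 (1.99), Cx3cr1 (2.72), Cxcr4 (1.20), Csf1r (2.91) and Nr4a1 (2.81), higher in that difference at 17 h, and Ly6c2 (-1.35), lower. Relative to the median gene Cxcr4 lay at -0.08, and the call for Ccr2 ended once a length trend was removed (adjusted p = 0.40), that for Ly6c2 after quantile normalization (adjusted p = 0.42). The 2 times are also 2 experiments in marrow, and in hepatocytes the labels do not say whether the 2 times were isolated together, so time is not separated from experiment or isolation.

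Among the 35 splits of the 7 marrow libraries at 17 h, only the real split called as many genes (8171, highest other 1), which argues against chance for that count. The same holds at 4 h (40, highest other 0, 1 of 35 splits) and in spinal cord (221, highest other 0, 1 of 35 splits). The share cannot fall below 1 of 35, so chance is not excluded. Without 1 library the counts ran from 14 to 145 at 4 h and from 22 to 745 in spinal cord. For CCR2-/- monocytes the 10 splits are too few (403; highest other 0, 1 of 10 splits). For the marrow interaction, 1 of 100 drawn splits, the real one, called as many genes (7782, highest other 7734). Splits that part the 17 h libraries as the real one does, and mix only those of 4 h, called 7566 to 7734. This count thus rests on the 17 h libraries and hardly depends on how those of 4 h are grouped, so the splits cannot exclude chance for an interaction.

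The count of 8171 genes at 17 h was weighed first. Values correlated with transcript length at -0.382 to -0.344 in fed and at 0.364 to 0.379 in fasted 17 h libraries, so this trend parted the groups. A trend with median transcript length is argued against as the whole cause. With each library's trend removed 6476 genes were called, and of the 8171 genes 5625 were called again, 4527 of them with the same sign. Degraded RNA might leave such a trend, and what it might leave beyond that trend was not tested. The split moved to 3293 up and 3183 down, and 2126 of the 8171 took the other sign. Centring on the median alone evened the split too (3737 up and 3323 down) and turned nearly as many signs. These shifts thus cannot tell a length trend from a shift of the median, and a part played by such a trend stays open. The fed libraries stand apart from all other marrow libraries: the highest mean correlation of any fed 17 h library with the fed libraries of the other experiments was 0.763, and the lowest of a fasted 17 h library was 0.940. An effect of 17 h of fasting on the fasted cells would leave the fed cells near other fed cells, so something that sets the fed 17 h libraries apart may make up much of the difference. What set them apart was not tested, and the labels name no batch.

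The lower inflammatory genes of fasted spinal cord monocytes were weighed against neutrophil RNA in fed libraries 1 and 2. For interferon-stimulated genes this is argued against: in the fed libraries with little neutrophil RNA the mean log2 value of the list was still 1.76 above the highest fasted library (5.57 against 3.82, with an SD of 0.486 over fasted libraries). A length trend is argued against too, with a camera adjusted p = 1.5e-22 once it was removed. That value is at the preset correlation. With an estimated one, and the trend not removed, the list did not pass (camera adjusted p = 0.11). For inflammatory mediators the same gap was 0.219, within the SD of 0.321, so neutrophil RNA may account for part of that fall, and this stays open. Fasting cycles, and a different mix of cells sorted from fed and fasted mice, stay open for both lists. Activation while cells were isolated was not tested and stays open too. The immediate early list was lower in fasted libraries, at a median of -1.21 relative to all genes (camera adjusted p = 1.8e-11, and adjusted p = 0.11 with an estimated correlation).

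The called genes near Ccr2 in CCR2-/- monocytes were weighed last. Of 12 measured genes within 1 Mb, 5 were called, 4 higher and 1 lower, an odds ratio of 15.8 against the rest of the genome (95% interval 3.92 to 57.9), which an effect of the deletion on its closest neighbors may account for. Of these, Lztfl1 and Lars2 were both at adjusted p = 0.0437, and the call for Ccr1 ended without CCR2-/- library 2 (adjusted p = 0.0786) or 3 (0.105). Between 1 and 10 Mb, where DNA of another strain kept around the deleted gene would still lie, 1 of 39 genes was called (odds ratio 0.581, 95% interval 0.0143 to 3.46). That interval is too wide to argue for or against such DNA, and the 2 explanations cannot be told apart within 1 Mb.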

How the results depend on the processing

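The alternatives listed for the processing were planned before the data were examined, except for median-centred libraries, removal of the length trend, a mean of at least 10 TPM for genes, fed spinal cord libraries 3 and 4 alone and genes listed at 0 left out, which were chosen after seeing the data. Values outside 1.5 times the main count, or past or short of a threshold, follow by setting; the cause was not tested for any of them, unless a smaller number of libraries or genes in the setting gives it. None of the 300 gene results counted below reversed. Over all genes some did, as given for marrow at 17 h, and the larger side of the split turned in 4 comparisons. It turned in hepatocytes at 12 h after quantile normalization and at a mean of at least 10 TPM, between fed hepatocytes after quantile normalization, median centring and removal of the length trend, for CCR2-/- without C57BL/6 library 2 or CCR2-/- library 2 or 3, and in spinal cord with fed libraries 3 and 4 alone or without fasted library 3 or 4. The values were taken as TPM, so what depth limits could not be tried, and where leaving out a library left a group with 1 sample, that sample was assumed to vary like the other groups. Of 4742 alternative values for 300 gene results, 4219 kept their direction and side of the threshold, 509 fell short of it and 14 passed it. Leaving aside the fits without 1 library, 74 of 86 counts of genes, 28 of 45 counts of lists and 14 of 20 correlations stayed within their limits.

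With the replicate number as a block, genes called were 1689 (461 up, 1228 down) in hepatocytes at 4 h, 1227 for the hepatocyte interaction, 3043 between fed hepatocytes, 1423 for CCR2-/- and 119 in spinal cord. The numbers do not pair the libraries: in no comparison did every sample correlate best with its own number except in hepatocytes at 4 h, with 2 pairs, so the block is no measure of a weaker effect. Hepatocytes at 4 h had 1744 genes with only the 5 libraries of that time. Without a trend in limma CCR2-/- had 48 (17 up, 31 down). In spinal cord 783 genes were called after quantile normalization, 687 in median-centred libraries, 632 without the length trend, 138 at a mean of at least 10 TPM and 774 (293 up, 481 down) with fed libraries 3 and 4 alone.

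Gene lists that passed with an estimated correlation were 0 in hepatocytes at 4 h, 5 at 12 h, 3 for their interaction, 2 between fed hepatocytes, 1 in marrow at 4 h, 0 at 17 h, 0 for the marrow interaction, 0 for CCR2-/- and 0 in spinal cord. With fry they were 27 (hepatocytes 4 h), 29 (12 h), 31 (fed hepatocytes), 32 (marrow 17 h), 30 (marrow interaction), 3 (CCR2-/-) and 6 (spinal cord), and with the block in camera 8 for the marrow interaction. Correlations of fold changes moved to 0.384 for hepatocytes at 4 h and 12 h after quantile normalization, to -0.320 (Spearman) for marrow at 4 h and 17 h, to 0.173 (length trend removed) for marrow at 4 h and spinal cord, and to -0.156 (mean of at least 10 TPM), -0.149 (Spearman) and -0.0697 (length trend removed) for marrow at 17 h and spinal cord.

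Without 1 library at a time, genes called ran from 2654 to 3976 and lists from 15 to 17 in hepatocytes at 4 h, 2449 to 3172 (lists 16 to 16) at 12 h, 1603 to 3731 (13 to 16) for the hepatocyte interaction and 4000 to 4826 (11 to 12) between fed hepatocytes. In marrow they ran from 14 to 145 (9 to 12) at 4 h, 8044 to 8177 (5 to 8) at 17 h and 7705 to 7777 (4 to 8) for the interaction, with 11 to 1060 (11 to 15) for CCR2-/- and 22 to 745 (20 to 22) in spinal cord. Correlations ran from 0.359 to 0.433 (hepatocytes 4 h and 12 h), -0.416 to -0.283 (marrow 4 h and 17 h), -0.431 to -0.273 (marrow 17 h and CCR2-/-), 0.166 to 0.234 (marrow 4 h and spinal cord) and -0.180 to -0.0790 (marrow 17 h and spinal cord). The lowest counts came without fed library 2 (marrow 4 h, 14), CCR2-/- library 3 (11), fasted library 3 (spinal cord, 22), and the highest without fasted library 1 (145), CCR2-/- library 1 (1060) and fed library 3 (745).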

Other observations

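The tests of genes shared between marrow and spinal cord, of Apoe and of cholesterol synthesis were chosen only after the results were seen.

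Fasting for 12 h also moved genes of drug metabolism in hepatocytes. Cyp2b10, a target of the nuclear receptor CAR, rose from 67.8 ± 4.83 to 470.3 ± 6.60 TPM (SD, n = 2 fed and 3 fasted; log2 fold change 2.78, SE 0.10, adjusted p = 4.9e-08), while Cyp1a2, which handles caffeine among others, fell from 494 ± 2.22 to 125 ± 4.45 TPM (log2 fold change -1.98, SE 0.05, adjusted p = 6.0e-09) and the glutathione transferase Gstm1 fell (log2 fold change -2.12, SE 0.05, adjusted p = 6.0e-09). Of 24 xenobiotic metabolism genes 14 fell and 5 rose (5 rose and 14 fell over the list alone; camera adjusted p = 1.7e-04, and adjusted p = 0.20 with an estimated correlation). Nr0b2, a repressor of bile acid synthesis, fell from 121 ± 4.10 to 8.72 ± 1.93 TPM (log2 fold change -3.67, SE 0.16, adjusted p = 1.6e-07), and Cyp8b1, an enzyme of that pathway, rose from 447 ± 21.3 to 1767 ± 23.0 TPM (log2 fold change 1.98, SE 0.08, adjusted p = 1.1e-07).

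In marrow monocytes fasted for 17 h the growth factor receptor Csf1r rose from 64.7 ± 18.2 to 410.2 ± 79.5 TPM (SD, n = 3 fed and 4 fasted; log2 fold change 2.67, SE 0.20, adjusted p = 6.6e-07), 1.49 above the median gene, and the integrin Itgam rose from 23.5 ± 5.85 to 284 ± 40.0 TPM (log2 fold change 3.56, SE 0.17, adjusted p = 1.0e-07), 2.37 above it. Plac8 fell from 5394 ± 74.9 to 976 ± 136 TPM (log2 fold change -2.48, SE 0.11, adjusted p = 9.6e-08). Across 8718 genes, which are not independent replicates, the fold changes at 17 h and those of CCR2-/- monocytes had a Pearson correlation of -0.369.

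Fasting of 4 h in marrow and fasting cycles in spinal cord called some of the same genes, although the tissues and the treatments differ. Of 8847 genes tested in both, 11 were called in both: 8 were higher in both (0.353 expected) and 2 lower in both, Idi1 and Sqle of cholesterol synthesis (0.0985 expected), and Rbm3 was lower at 4 h and higher in spinal cord. Fisher's exact p for those higher in both was 1.1e-09, across genes that are not independent. A response to fasting shared by both monocyte populations may account for this overlap. The 8 genes were Chil3, Chil4, Fkbp5, Klf9, Lifr, Ms4a8a, Per1 and Sult1a1. Chil3 and Chil4 are near-identical copies, so their calls may not be separate. Fkbp5, Klf9, Per1 and Sult1a1 are members of the glucocorticoid response list, and Per1 is also a clock gene. Other causes that move such genes were not tested. The fold changes of all genes were only weakly related (Pearson correlation 0.20). At 4 h the calls for Idi1 and Sqle were near the threshold (adjusted p = 0.046 and 0.047; over their alternatives 0.0278 to 0.152 and 0.0328 to 0.157). There the call for Idi1 ended without fasted library 2, 3 or 4 or fed library 1, 2 or 4 (adjusted p 0.0698, 0.13, 0.089, 0.0831, 0.152 and 0.115), and that for Sqle without fasted library 2, 3 or 4 or any of the fed ones (0.0576 to 0.157). In spinal cord the call for Idi1 ended without fasted library 2, 3 or 4 (0.0677, 0.0887 and 0.0809) and that for Sqle without fed library 1 (0.0535) or fasted library 2, 3 or 4 (0.106, 0.125 and 0.108).

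Apoe was higher in fasted marrow monocytes at both times. At 4 h it was at 1278 ± 157 TPM (SD, n = 4) in fasted and 762 ± 202 TPM (SD, n = 4) in fed monocytes, not past the test in limma (log2 fold change 0.77, SE 0.16, adjusted p = 0.079), with an exact permutation p = 0.0286 over 70 arrangements. At 17 h it rose by 2.87 on the log2 scale, with an exact permutation p = 0.0571 over 35 arrangements. Each p doubles the smaller tail and is the smallest that its number of arrangements can give that way. The gene was picked for its higher values in fasted libraries, so these p restate that the groups do not overlap, and whether it responds to fasting at both times stays open.

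Cholesterol synthesis genes stood below other genes in fasted hepatocytes at 4 h and 12 h (-0.92 and -2.83), in marrow monocytes at 4 h and 17 h (-0.45 and -0.46) and in spinal cord monocytes (-0.89), so that the highest of the 5 medians relative to all genes was -0.45. At 17 h the list did not pass (camera adjusted p = 0.23, and adjusted p = 0.67 with an estimated correlation), 11 of its 18 genes rose and 5 fell, and its own median was 0.72. That median depended on scaling. It was -0.63 after quantile normalization, where the list passed as lower (camera adjusted p = 0.035). It was -0.41 once a length trend was removed, where the list did not pass (camera adjusted p = 0.13). The list also stood low in fed CCR2-/- monocytes (-0.13). The common direction was seen before it was tested, so whether it is a shared response to fasting stays open.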
